A study of Mus musculus with 6 samples.

How the data were processed

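Gene expression was measured in mouse colon epithelium with Affymetrix Mouse Genome 430 2.0 arrays, each of which reads transcripts through probe sets, small groups of short probes. Per the labels' protocols, mice were 12 weeks old and of mixed 129SvEv/C57BL/6/DBA/2 background. The opened intestine was soaked in 3 mM EDTA and 0.05 mM DTT for 1.5 to 2 hours, the epithelium was shaken off the muscle, and cells were pelleted without sorting. RNA from several mice was pooled, and 30 ng of total RNA was amplified with the NuGEN WT-Ovation pico kit. Amplification from so little RNA, pooling and the lack of a sort all bear on the values: low transcripts can be read unevenly, differences between single mice are averaged away, and any lymphoid or connective tissue that comes off with the epithelium is measured with it.

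The deposited values are log2 expression values made by the authors with RMA (background correction, quantile normalization and probe summary on the log2 scale), per the submitters' processing notes, which give no version. The log2 scale was read from the values, which ran from 1.78 to 14.4. Scanner files, scan dates and detection calls were not analysed here, so array batches could not be tested and no background cut was applied. Within each array, 3230 to 3548 probe sets shared their exact value with another probe set (7.16% to 7.87%). Array medians lay between 5.44 and 5.58, and correlations between arrays over all probe sets between 0.975 and 0.990. Arrays have no read depth; their number, 3 per group, limits the precision.

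Groups came from the genotype in the labels: 3 arrays of knockout epithelium (replicates 1, 2 and 3, pools of 3, 2 and 2 mice) and 3 of wild type (replicates 4, 5 and 6, pools of 3 mice each). Each array is a separate pool, so the p-values measure the spread between pools. The table held 45101 probe sets. In the platform annotation 34958 had 1 gene symbol, 932 had several and 9211 were unnamed; 64 carried control names. Of those with 1 symbol, 34754 matched the RefSeq gene table of assembly GRCm38.p6 by gene number, and 0 symbols needed updating. Probe sets with several symbols or none were left out of the gene-level tests. Each gene took the probe set with the highest mean over the 6 arrays, with no filter on low values, which left 18194 genes, 9012 of them with more than 1 probe set. No coordinates are given, because no genome build is named for the array values.

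Knockout was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are knockout minus wild type on the log2 scale, with limma's standard error (SE) and 95% intervals. Gene lists were tested with limma's camera, which asks whether a list's genes stand higher or lower than the other genes, with a preset correlation between genes of 0.01, at least 5 measured genes and adjustment over 33 lists. A list's value is the median log2 difference of its genes. Its level in an array is the median over its genes of the value relative to each gene's 6-array mean. The comparisons, the lists (897 members, 828 measured), the rule for named genes and most of the other settings tried were fixed before the data were examined.

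The rule named the targeted genes, Axin2, Lgr5, Ascl2, Sox9, Myc, Ccnd1 and Cd44, up to 10 genes passing in each direction, or where fewer than 5 passed those with the smallest unadjusted p up to 5, and up to 4 members of each list that passed, by unadjusted p in the list's direction. Predicted genes were counted but not named. Genes outside this rule are named as such.

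The tests were checked on simulated data for this comparison, with 200 of the 18194 genes changed in each of 20 simulations. The fit recovered 58.4% of 2-fold, 92.5% of 4-fold and 97.1% of 8-fold changes, with 5.63% of calls false. These rates hold for 200 changed genes, and fewer were not simulated. They also hold for arrays of equal spread. An array set apart from the others, as wild type 6 was here, was not simulated. With fewer changed genes the adjustment asks for a smaller p and recovers less. A result of 0 calls therefore does not show that large changes are absent. A shift of 0.3 added to the Wnt target list was called in 20 of 20 simulations, and 1.25% of the tests of the other lists were calls. These simulations drew genes independently of each other, so they do not show how the list test behaves with correlated genes.

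Alternatives covered cyclic loess on top of the deposited values, brighter genes only, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, an intensity trend with robust estimation, array weights, the number of mice as a covariate (which varies only among the knockouts, so that this fit compares knockout 1 alone with wild type), leaving out each array, leaving out genes within 20 Mb of the targeted genes, each probe set tested alone, a 1.5-fold minimum, a threshold of 0.1, camera with an estimated correlation, and fry, a rotation test of a list on its own. Figures were drawn with matplotlib.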

Results

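Epithelium from the colon of mice lacking Bcl9 and Bcl9l in the intestine (vil-Cre-Bcl9-/-/Bcl9l-/-) was compared with that of wild-type mice on expression arrays. BCL9 and BCL9L are co-activators that bind beta-catenin, the transcriptional effector of the Wnt pathway, and vil-Cre drives recombination in the intestinal epithelium. The comparison addresses which genes, and in particular which Wnt target and stem cell genes, change in healthy colon when both co-activators are lost. Without single knockouts, the share of each co-activator cannot be told apart. The labels name vil-Cre only for the knockouts, so an effect of Cre itself cannot be told apart from loss of the co-activators. Nor can strain alleles that differ between the groups on the mixed background. There were 6 arrays, 3 per genotype, each from a pool of 2 or 3 mice. The main spread among them did not follow genotype. The leading principal component held 38.7% of the variance and set wild type 6 (50.7) apart from the other 5 arrays (-22.6 to -1.26). The next component, with 22.1%, did separate the genotypes. For 3 against 3, chance gives such a separation in 10% of cases on any single component. This component read 11.2 to 16.9 in the knockouts, -35.7 in wild type 5 and -4.01 and -3.11 in the other wild-type arrays, so wild type 5 lay farthest out.

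The targeted genes differed between genotypes by less than the test could call. Bcl9 measured 7.28 ± 0.26 (SD, n = 3) in the knockouts and 7.17 ± 0.29 (SD, n = 3) in wild type, a difference of 0.11 (95% interval -0.36 to 0.58, limma adjusted p = 0.977). Bcl9l measured 8.15 ± 0.10 against 7.94 ± 0.24, a difference of 0.22 (-0.14 to 0.57, limma adjusted p = 0.954). The other Bcl9 probe set differed by -0.04, and the other Bcl9l probe sets by 0.15 and -0.20. Whether any of these probes lies in the deleted part of its gene is not given in the sources used here. A probe outside that part need not read lower in a knockout, so these values neither bear out nor contradict the labels.

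No gene passed the test. limma called 0 of 18194 genes higher and 0 lower (smallest adjusted p = 0.291). At an unadjusted p under 0.05 there were 857 genes, 490 higher and 367 lower, which is 4.71% of those tested where chance alone gives 5%. Knockout and wild-type values did not overlap for 1878 genes, or 10.3%, where chance gives 10% for 3 against 3. The 95% interval of a typical gene extended 0.36 either side of its difference. Without wild type 6, limma called 3 genes, namely Lrg1 (3.61), Pla2g2a (2.65) and Vav3 (-1.58), of which Lrg1 and Vav3 are outside the naming rule and were chosen after their values were seen.

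Among the genes with the smallest unadjusted p, none of which passed, Pla2g2a, a secreted phospholipase with antibacterial activity, read 9.47 ± 0.09 in the knockouts and 7.12 ± 0.56 in wild type (SD, n = 3 each), 5.09-fold higher (2.35, SE 0.27, limma adjusted p = 0.291). Cma1, a mast cell chymase, differed by 1.47 (SE 0.18), Acpp, an acid phosphatase, by 1.43 (SE 0.17), Khdc1a by 2.67 (SE 0.42) and the beta-defensin Defb45 by 1.42 (SE 0.24). On the lower side, the deubiquitinase Otud1 differed by -2.61 (SE 0.28), Amotl1, of the angiomotin family, by -1.70 (SE 0.20), Vav2 by -1.94 (SE 0.25), Cps1, a mitochondrial enzyme of the urea cycle, by -1.89 (SE 0.25) and the small GTPase Rab30 by -0.94 (SE 0.13). The adjusted p of these 10 genes ran from 0.291 to 0.915. Several readings were dim against array medians of 5.44 to 5.58. Knockout means were 4.22 for Otud1, 4.55 for Vav2 and 4.28 for Rab30, and the wild-type mean of Khdc1a was 4.27. No detection call was used, so these readings are not shown to be above background. Other probe sets of Acpp, Amotl1, Vav2 and Rab30 differed less, with values as near 0 as 0.60, -0.39, -0.11 and -0.05.

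The Wnt target list was not called in either direction. The median difference of the 31 measured genes was -0.018, with 13 above and 18 below 0 (limma camera adjusted p = 0.848; adjusted p = 0.989 with an estimated correlation). With the brightest probe set of each gene, 0 members passed over all genes and 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05. Axin2, a negative regulator of the pathway and a widely used readout of it, differed by 0.09 (SE 0.16). The other readouts differed by -0.13 (SE 0.18) for Myc, 0.29 (SE 0.16) for Ccnd1, which encodes cyclin D1, -0.08 (SE 0.19) for Cd44 and -0.02 (SE 0.18) for the transcription factor Sox9. The other Ccnd1 probe sets differed by 0.18 and 0.46 (limma unadjusted p = 0.34 and 0.0078), and Ccnd1 was 0.13 without wild type 6. Other probe sets differed by -0.43 to -0.035 for Cd44, where the -0.43 came from a dim one (mean 2.88). They differed by 0.17 and 0.096 for Sox9 and by -0.00026 for Axin2. None of these passed over all probe sets.

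The 26 measured stem cell markers had a median of -0.015, with 11 above and 15 below 0 (limma camera adjusted p = 0.585; adjusted p = 0.975 with an estimated correlation). Again with the brightest probe sets, 0 members passed over all genes and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05. Ascl2, a transcription factor of crypt base stem cells, differed by -0.25 (SE 0.26), and by -0.24 and 0.29 in its other probe sets. It was -0.08 without wild type 5 or without knockout 3, and -0.51 without wild type 6. Lgr5, the receptor that marks these cells, has 2 probe sets that differed in what they read. The one with the highest mean gave 3.62 ± 0.15 in the knockouts and 3.96 ± 0.34 in wild type (SD, n = 3 each), a difference of -0.34 (SE 0.19, limma adjusted p = 0.953). Without wild type 5 this difference was -0.15.

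The other Lgr5 probe set, chosen after its values were seen, had the smallest unadjusted p of all probe sets on the array. It gave 2.82 ± 0.23 in the knockouts and 4.71 ± 0.19 in wild type (SD, n = 3 each), a difference of -1.89 (95% interval -2.29 to -1.50). It did not pass over all probe sets (limma adjusted p = 0.328). With this probe set standing for Lgr5, the gene did not pass over all genes (limma adjusted p = 0.162). It was then the 1 member passing when adjusted over the list alone (limma adjusted p = 0.000276 among Wnt target genes and 0.000232 among stem cell markers), but the probe set was singled out for its small p, which that adjustment leaves out of account, so these values are not independent evidence. Both probe sets have low means, near the 26th percentile of the array, and the knockout mean of this one lies at the 9.96th percentile of the knockout values. No detection call was used, so these readings are not shown to be above background.

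**Figure D1:**
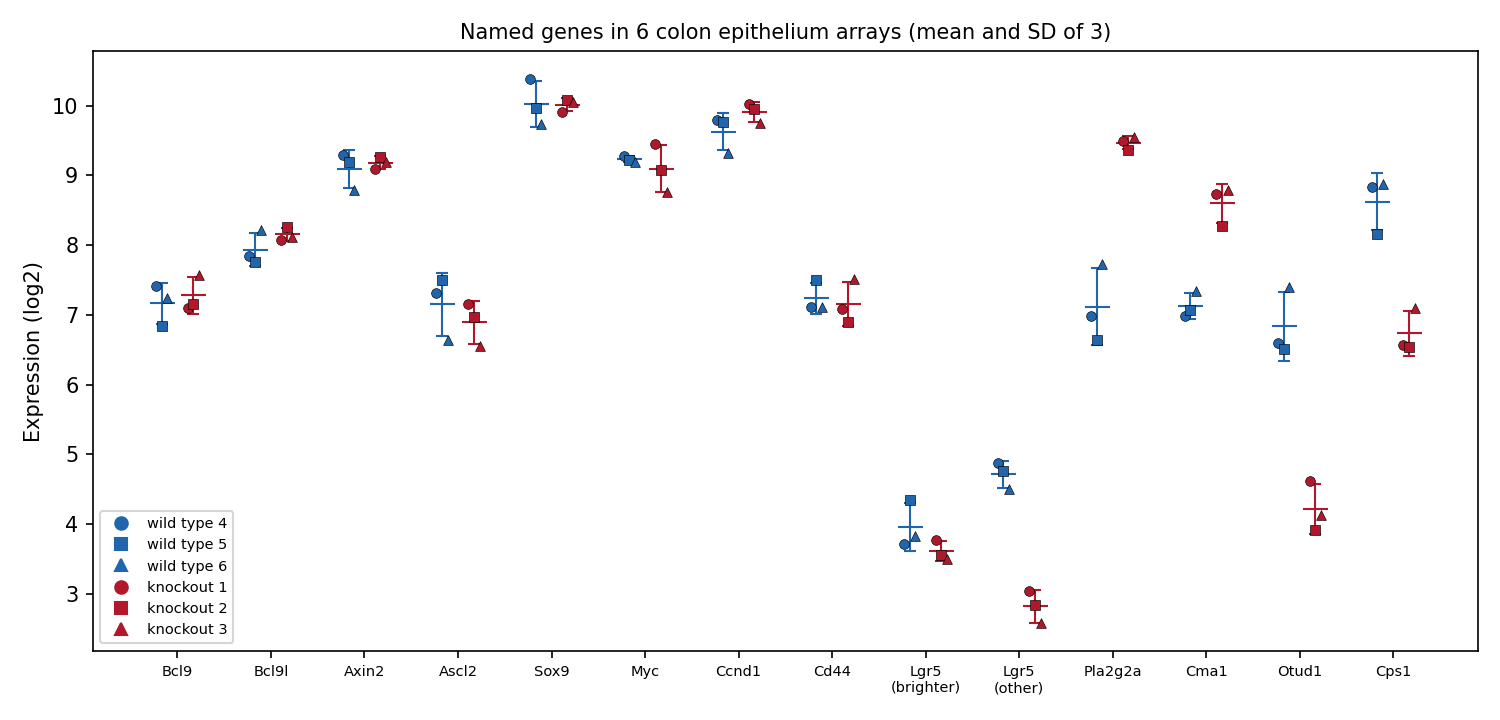
Expression (log2) of the targeted genes, the Wnt and stem cell genes named in advance, both Lgr5 probe sets (the one with the highest mean, marked brighter, and the other) and 4 of the genes with the smallest unadjusted p, in 3 wild-type (blue) and 3 knockout (red) arrays. Points are arrays, horizontal bars the mean and error bars the SD of 3; the knockout arrays of the other Lgr5 probe set read 2.58 to 3.04 and the wild-type arrays 4.50 to 4.88, while none of these genes passed limma's test.

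Of 33 gene lists, 8 passed limma's camera test with the preset correlation, 2 higher and 6 lower in the knockouts. With the B and plasma cell level of each array as a covariate, a setting chosen after seeing the data, 6 passed, 5 higher and 1 lower, and 3 of these were among the 8; the B and plasma cell list itself has no test there. With the correlation estimated from the arrays 0 lists passed (smallest adjusted p = 0.391; 2 lists at an unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p = 0.418; 3 lists at an unadjusted p under 0.05). No call therefore holds with an estimated correlation. No list member passed over all genes.

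Cholesterol synthesis genes stood higher. All 20 measured members were above 0, with a median of 0.22 (limma camera adjusted p = 1.7e-09; adjusted p = 0.649 with an estimated correlation). Of them 8 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone, Mvd of the mevalonate pathway at 0.51 (SE 0.11). Sqle, which makes squalene epoxide, differed by 0.44 (SE 0.13), Fdft1, which makes squalene, by 0.38 (SE 0.11) and Insig1, which restrains SREBP processing, by 0.34 (SE 0.11). Of the other Fdft1 probe sets the next brightest differed by 0.37 and the dim ones by -0.11 and -0.035. List levels were -0.24 to -0.07 in the wild-type arrays and 0.04 to 0.21 in the knockouts. In a fit that sets knockout 1 alone against wild type the list was not called (0.18, adjusted p = 0.057).

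Tuft cell markers stood lower. Tuft cells are rare chemosensory cells of the epithelium. Of 21 measured markers 17 were below 0, with a median of -0.24 (limma camera adjusted p = 2.84e-05; adjusted p = 0.391 with an estimated correlation). Dclk1 differed by -1.33 (SE 0.33), Sh2d6 by -0.59 (SE 0.15) and the transcription factor Gfi1b by -0.55 (SE 0.14), and these 3 passed when adjusted over the list alone. The 8 other Dclk1 probe sets differed by -1.55 to -0.0072. Alox5ap, which is needed for leukotriene synthesis, differed by -1.01 (SE 0.30). List levels were -0.28 to 0.03 in the knockouts and 0.08 to 0.23 in wild type. In a fit that sets knockout 1 alone against wild type the list was not called (-0.12, adjusted p = 0.0726).

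Cell cycle genes had a median of 0.19, with 22 of 35 above 0 (limma camera adjusted p = 0.0466; adjusted p = 0.975 with an estimated correlation). The mitotic genes Cenpf (0.53, SE 0.15), Birc5 (0.50, SE 0.21), Ccnb2 (0.40, SE 0.20) and Aurka (0.51, SE 0.28) led the list, and 0 members passed when adjusted over the list alone. Aurka ran from 0.33 without knockout 1 to 0.85 without knockout 2, where Ccnb2 was 0.63. The other Aurka probe set (mean 4.24) differed by 0.037. The other Cenpf probe sets differed by 0.47 (mean 7.70) and 0.20 (mean 3.89). Without knockout 3, whose level was 0.35 against -0.16 to 0.02 in the other knockouts, the median was 0.014 and the test pointed the other way, and without any 1 wild-type array the list was not called (adjusted p = 0.073 to 0.148). Immediate early and stress genes had a median of -0.16, with 27 of 35 below 0 (limma camera adjusted p = 0.00225; adjusted p = 0.391 with an estimated correlation). Nr4a1 differed by -0.55 (SE 0.16), Ier5 by -0.38 (SE 0.13), the heat shock gene Hspa1b by -1.03 (SE 0.38) and Klf6 by -0.29 (SE 0.14; other probe sets of Ier5 and Klf6 came as near 0 as -0.028 and -0.040), with 0 passing when adjusted over the list alone. Without wild type 6 the list was not called (-0.13, adjusted p = 0.118), and without wild type 4 the median was -0.070. Klf6 was -0.17 without knockout 1.

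The other lists called lower were of lymphocytes, connective tissue and interferon response, and wild type 6 had the highest level in each. B and plasma cell markers had a median of -1.11 and all 22 lay below 0 (limma camera adjusted p = 1.19e-07; adjusted p = 0.721 with an estimated correlation). The level of this list was 2.43 in wild type 6 and -0.66 to -0.10 in the other 5 arrays, with wild type 5 below every knockout. Spib differed by -1.44 (SE 0.61), Derl3 by -0.74 (SE 0.33), the B cell receptor component Cd79a by -1.74 (SE 0.83) and the B cell co-activator Pou2af1 by -2.54 (SE 1.35). Single arrays moved each of these: Cd79a was -0.70 and Pou2af1 -0.81 without wild type 6, Derl3 -0.37 without wild type 5 and Spib -0.81 without knockout 2. Without wild type 6 the median was -0.20 and the list was not called (adjusted p = 0.0727).

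Markers of T cells and intraepithelial lymphocytes had a median of -0.46, with 24 of 25 below 0 (limma camera adjusted p = 1.19e-07; adjusted p = 0.721 with an estimated correlation). Itgae, the integrin that holds lymphocytes in epithelium, differed by -0.74 (SE 0.16), Il2rb by -0.89 (SE 0.24), Nkg7 by -0.46 (SE 0.15) and Zap70 by -0.31 (SE 0.12). The other Itgae probe set differed by -0.0047, the other Il2rb probe set by -0.15, and the other Zap70 probe sets by -0.14 and -0.058. The level was 0.67 in wild type 6 and at most 0.03 elsewhere, and without that array the median was -0.18 (adjusted p = 0.139). Fibroblast markers had a median of -0.23, with 19 of 24 below 0 (limma camera adjusted p = 0.000973; adjusted p = 0.721 with an estimated correlation). The collagen gene Col1a2 differed by -0.87 (SE 0.34), Dcn by -1.16 (SE 0.48), Igfbp4 by -0.61 (SE 0.26) and Fbln2 by -0.27 (SE 0.12). Without wild type 6 Col1a2 was -0.51 and Igfbp4 -0.35, and without knockout 2 Dcn was -0.70. The other Igfbp4 probe sets differed by -1.93 to -0.26, and the other Col1a2 and Dcn probe sets came as near 0 as -0.11 and -0.033. The level was 0.39 in wild type 6, and without it the median was -0.13 (adjusted p = 0.415). The fibroblast call was also lost without knockout 2 (-0.15, adjusted p = 0.0898). In the B cell, T cell and fibroblast lists 0 members passed when adjusted over the list alone. Most members of these 3 lists were dim. In the 5 arrays other than wild type 6, 2 of 22 B cell, 4 of 25 T cell and 5 of 24 fibroblast markers lay above the median gene. Fbln2 read only 3.27 in the knockouts and 3.54 in wild type, and no detection call was used.

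Interferon response genes had a median of -0.33, with 29 of 37 below 0 (limma camera adjusted p = 1.19e-07; adjusted p = 0.721 with an estimated correlation). Ifi27l2a differed by -2.10 (SE 0.39) and was the 1 member that passed when adjusted over the list alone. Irf7, a transcription factor of the response, differed by -0.71 (SE 0.18), Xaf1 by -0.94 (SE 0.34) and Ifit1 by -0.99 (SE 0.40). The other Xaf1 probe set differed by -2.53, and Ifit1 was -0.65 without wild type 5. Levels overlapped between genotypes: -0.77, 0.03 and 0.05 in the knockouts, -0.37, 0.28 and 0.70 in wild type. The call was lost without wild type 6 (-0.22, adjusted p = 0.121) and without knockout 1 (-0.26, adjusted p = 0.2), and the median was -0.52 to -0.58 without knockout 2, knockout 3 or wild type 4.

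**Figure D2:**
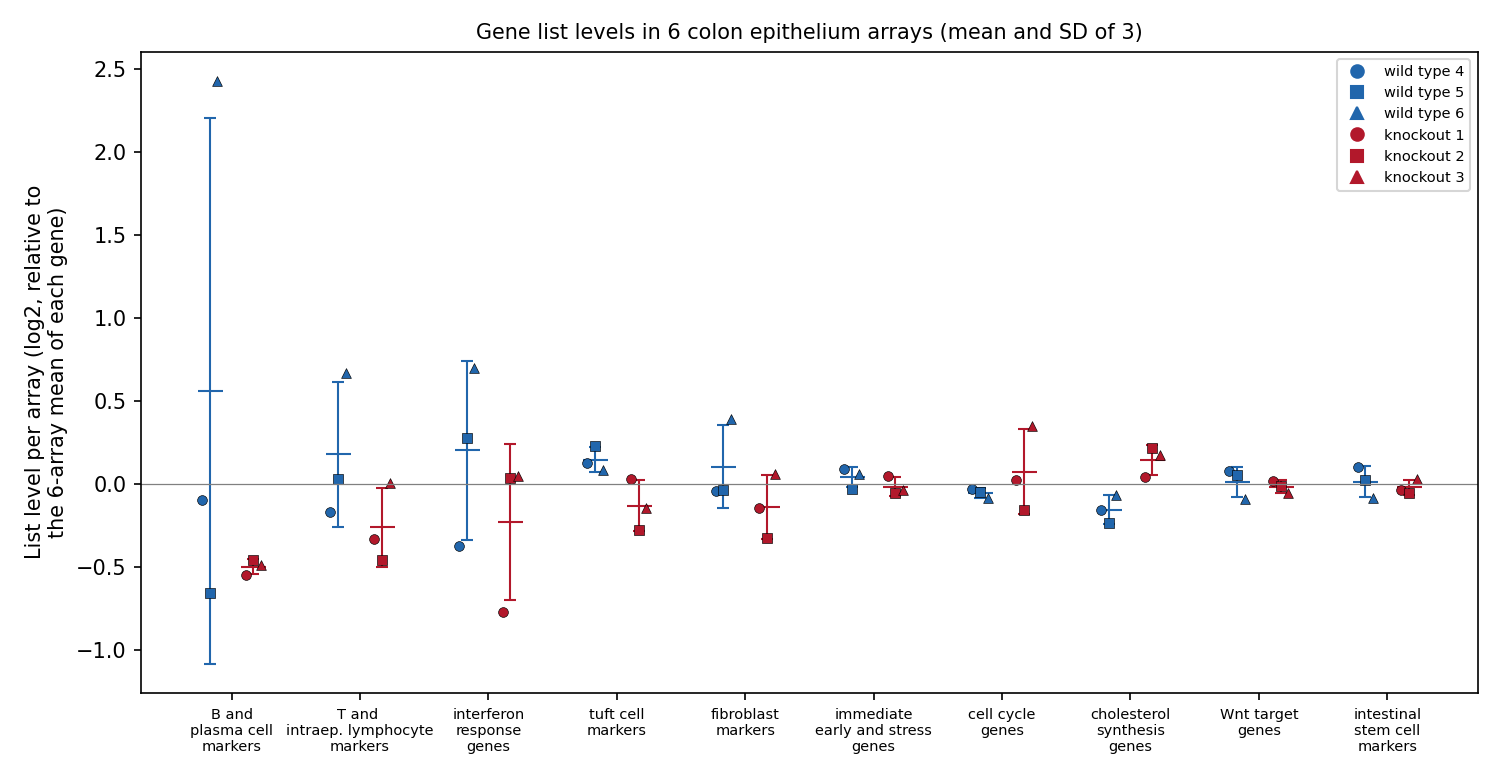
Level of each called list, and of the Wnt target and stem cell lists, in each array (log2, median over the list's genes relative to their 6-array means), with wild type in blue and knockout in red. Points are arrays, horizontal bars the mean and error bars the SD of 3; wild type 6 reads 2.43 for B and plasma cell markers against -0.66 to -0.10 in the other arrays, while the cholesterol synthesis and tuft cell lists separate the genotypes, as 4 of all 33 lists do where chance gives 10%.

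The remaining 23 lists did not pass. Among epithelial cell types the median was -0.012 for goblet cell markers (limma camera adjusted p = 0.845), -0.027 for absorptive colonocyte markers (0.472 for the adjusted p), 0.015 for enteroendocrine cell markers (0.981) and -0.0029 for markers of Paneth and deep crypt secretory cells (0.86), a list in which Pla2g2a alone passed when adjusted over the list alone. Epithelial genes had a median of 0.019 (adjusted p = 0.981), small intestine genes 0.0051 (0.845), squamous epithelium markers -0.012 (0.981) and genes of distal colon and posterior patterning -0.042 (0.857). In signalling, Wnt pathway components had a median of 0.013 (adjusted p = 0.773), Notch pathway genes 0.023 (0.756) and BMP and hedgehog genes 0.0055 (0.774).

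Medians of the other tissue and immune lists were -0.12 for mesenchymal transition genes (limma camera adjusted p = 0.0767), -0.14 for smooth muscle (0.0688), -0.13 for endothelium (0.179), -0.059 for enteric neurons and glia (0.571), -0.098 for macrophages and dendritic cells (0.488), 0.012 for neutrophils (0.7), 0.025 for MHC class II genes (0.69) and -0.076 for red blood cells (0.378), where only 8 of 16 members were measured. Metabolic and stress lists had medians of 0.055 for PPAR and fatty acid oxidation genes (adjusted p = 0.748), -0.0033 for xenobiotic and glutathione genes (0.69), 0.031 for the unfolded protein response (0.981) and 0.068 for antimicrobial and inflammatory epithelial genes (0.562). In these 23 lists other than the Paneth list, 0 members passed when adjusted over the list alone. The median, the mean and the test differed in sign in 10 lists: enteroendocrine, Paneth, epithelial, neutrophil, squamous, small intestine, MHC class II, PPAR, Notch, and BMP and hedgehog.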

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

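No paired analysis was possible because the replicate numbers differ in every sample (1 to 3 in the knockouts, 4 to 6 in wild type). Alternatives using the B cell level, every probe set in the list test or other probe sets were chosen after seeing the data. Of 1439 alternative values, 1373 kept their side of the threshold and, where called, their direction. Of the rest 40 lost a call, 14 gained one, 9 counts moved by over 1.5 times and 3 reversed. Most of the 1439 belong to results never called, which seldom can change side. Of the 140 alternative values of called lists, 99 kept the call, 40 lost it and 1 reversed. Over all 1439 values, 147 changed direction, 1 of them a called list (cell cycle) and the others results that had not been called. The Bcl9, Bcl9l, Wnt target and stem cell results passed in no alternative (Wnt target median -0.087 to 0.021, stem cell -0.17 to 0.033). Leaving out genes near the targeted loci gives no value for Bcl9 or Bcl9l. The fit with mice per pool as a covariate compares knockout 1 alone with wild type, because the other knockouts are the only pools of 2 mice; it says nothing about pool size, and assumes that the lone pool varies like the others. With limma, genes changed stayed at 0 except for 1 (Spty2d1, outside the naming rule) with mice per pool as a covariate, 3 with the B cell level as a covariate (Lrg1, Pla2g2a and Plscr2), and 0 to 3 when 1 array was left out, the 3 without wild type 6. Of the genes named by the rule, Pla2g2a passed in 2 alternatives and no other did in any. The genes at unadjusted p under 0.05 numbered 857, 468 with brighter genes only (fewer genes tested) and 661 to 1086 when 1 array was left out.

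Lists called numbered 8, and 5 with brighter genes only (4 of the 8 and smooth muscle; tuft, T cell and B cell lists then had too few genes to test), 4 with mice per pool, 0 with an estimated correlation, 0 with fry, and 2 to 11 when 1 array was left out, where the 2 without wild type 6 (cholesterol synthesis and tuft) were among the 8. fry adjusted p was 0.953 for the cell cycle, fibroblast, B cell and interferon lists, 0.896 for T cells, 0.473 for stress, and 0.418 for tuft and cholesterol; the medians (0.19, -0.23, -1.11, -0.33, -0.46, -0.16, -0.24 and 0.22) do not depend on the list test. The cell cycle list lost its call with cyclic loess (0.12), brighter genes (0.20), the mean of probe sets (0.070), no _x_at or _s_at sets (0.14), mice per pool (0.081) and every probe set (0.042). With knockout 1 alone in the mice per pool fit, tuft (-0.12), stress (-0.082) and cholesterol (0.18) were not called either, while the interferon response genes list went to -0.95 and stayed called and the MHC class II genes list, not called, went to -0.60. The array weights ended the fibroblast call (-0.098) and moved the B cell median to -0.68 and the T cell median to -0.26, both still called. The fibroblast markers list stayed called at -0.35 with brighter genes and -0.13 with every probe set. The B cell level ended the fibroblast (-0.060), T cell (-0.13), interferon (-0.22) and stress (-0.070) calls and turned the tests of macrophage (0.13) and MHC class II (0.54) genes from lower to higher, past the threshold. With 1 array left out, medians ran from 0.014 to 0.27 for cell cycle (reversed test without knockout 3), -0.30 to -0.13 for fibroblasts (lost without knockout 2 or wild type 6), -0.68 to -0.18 for T cells, -1.65 to -0.20 for B cells, -0.58 to -0.22 for interferon and -0.20 to -0.070 for stress. Lists not called that passed in some setting were the smooth muscle markers list (-0.18 with brighter genes; -0.27 to -0.097 with 1 array left out, passing without knockout 3 or wild type 5), the mesenchymal transition genes list (-0.14 with every probe set; -0.13 to 0.00024 with 1 array left out, passing without knockout 1 or wild type 5), the antimicrobial and inflammatory epithelial genes list (0.083 with the B cell level, 0.12 with every probe set), and, with 1 array left out, the absorptive colonocyte markers list (-0.045 to 0.012, passing without knockout 2), the macrophage and dendritic cell markers list (-0.21 to 0.056, passing without wild type 4 or 5) and the MHC class II genes list (-0.11 to 0.20, passing without wild type 5). The cause was not tested, except as weighed for wild type 6 under the other observations. Signal over background limits low genes such as Lgr5.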

Other observations

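The tests of wild-type pool 6, of genotype for the B cell list, of fewer stem cells, of Paneth cells and of the number of genes changed over other splits were chosen only after the results they bear on were seen.

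The 30 measured antimicrobial and inflammatory epithelial genes had no common direction that was called, with a median of 0.068, 18 above and 12 below 0 (limma camera adjusted p = 0.562). The single genes named here were chosen after their values were seen, and none passed. Reg3g, an antibacterial lectin, read 10.3 ± 1.10 in the knockouts and 7.50 ± 1.76 in wild type (SD, n = 3 each; 2.77, SE 0.92), and the chemokine Cxcl1 differed by 1.18 (SE 0.27), while the alarmin Il33 differed by -1.70 (SE 0.49). The tight junction gene Cldn4 differed by -1.19 (SE 0.30). Each of these 4 had a limma adjusted p = 0.953.

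The lower B and T cell lists in the knockouts rest largely on wild type 6. Of 22 B cell genes 20 were highest there, among them Pou2af1 (10.3 against a mean of 4.67 in the other 5 arrays), Tnfrsf13c (10.5 against 6.41) and Cd79b (8.92 against 4.16), and 1 of the 22 is in another list. Of 25 T cell genes 18 were highest in wild type 6. Without that array the median went from -1.11 to -0.196 for B cells and from -0.459 to -0.178 for T cells, and both calls ended, so a lymphoid follicle taken up in that pool, which was not sorted, is a candidate explanation. For fibroblasts the median went from -0.226 to -0.126, and that call also ended without knockout 2 (-0.146), which leaves the explanation open. Among the T cell genes named for their small p, Nkg7 read 4.94 in wild type 6 against 5.12 and 5.42 in the other wild-type arrays. Zap70 read 5.61 there against 5.75 and 5.71, and Itgae 7.88 against 8.07 and 7.85. Il2rb was highest in wild type 6, at 5.85 against 5.17 and 5.23. Each of these genes read lower in every knockout than in every wild-type array. Being picked for a small p favours such a separation, which 10.3% of all genes show, so it is not evidence for genotype. The T cell list level overlapped between genotypes, at 0.002 in knockout 3 and -0.17 in wild type 4. A genotype effect on T cells was not settled and stays open. A genotype effect on B cells also stays open. Of the 2 other wild-type arrays, wild type 4 lay above every knockout and wild type 5 below every knockout, so they point opposite ways.

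The low reading of the second Lgr5 probe set in the knockouts did not come from wild type 6, as the difference was -1.997 without it and -2.001 to -1.77 over the 6 fits that leave out 1 array. Fewer stem cells may be an explanation, but the other 25 stem cell markers had a median of -0.013 (-0.37 to 0.44), and markers shared with other crypt cells would hide the loss of a rare type. Over 10 splits of the 6 arrays, too few for a share under 0.05, 2, the real one included, had a smallest p of 1.17e-05 (the real value) or less, and the smallest of the others was 6.36e-07. The brighter Lgr5 probe set differed by -0.34, and which of the 2 reads the transcript better was not tested.

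Pla2g2a was higher in every knockout than in every wild-type array. If more Paneth or deep crypt secretory cells were the explanation, the list's other 12 markers might rise with it. The 75th percentile of their differences was 0.15 and the highest 0.59, against 2.35, so the list as a whole did not rise as Pla2g2a did. The list mixes markers of both cell types, and markers shared with other crypt cells would hide a rise. More cells of either type therefore stay open. A strain allele may be an explanation, as Pla2g2a is known to be disrupted in some of the parent strains; 4 of 151 genes within 5 Mb (2.65%, on GRCm38.p6) had an unadjusted p under 0.05, against a 95th percentile of 7.28% over windows of that size, which leaves it open since neighbours need not differ in expression. An effect of genotype was not tested separately and stays open.

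The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For genes changed, all 10 splits must give at least the real 0, so that count tests nothing; the highest other gave 1. For lists called, 6 splits, the real one included, gave at least the real 8, and the highest other gave 13.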
